A study of Mus musculus with 4 samples.

How the data were processed

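The series holds 4 CLIP-seq samples from mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos. CLIP-seq crosslinks proteins to RNA with ultraviolet light, precipitates 1 protein and sequences the RNA fragments bound to it. Per the labels' protocols, the SR proteins SRSF1 and SRSF2 carried an HA tag in tetracycline-repressible MEF lines, the precipitation used an antibody against the tag, and the libraries were sequenced on Illumina instruments. SRSF1 was measured in the SRSF1 line and SRSF2 in the SRSF2 line, so the protein and the cell line cannot be told apart. For each of the 2 proteins, 1 library with 1 peak list was analysed. The SRSF1 libraries from cells given a control siRNA or an siRNA against SRSF2 were not analysed here and enter no comparison.

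For each of these 2 samples the authors deposited 1 list of peaks, with chromosome, start, end, name, score and strand. Coordinates are on mm9 per the submitters' processing notes, and are given here 1-based. The aligner, the peak caller and its threshold are not given in the sources used here. The deposited score is a whole number of at least 4, and what it measures is not given in the sources used here. The lowest score per host unit ran from 4 to 168 in the SRSF1 list and from 4 to 205 in the SRSF2 list, so scores may not be comparable between units. The score was used to rank or filter peaks within a list. The naming rule for overlapping pairs, which takes the smaller of both scores, is the exception. The name of each peak gives a host unit and a peak number. A host unit is a RefSeq transcript, a UCSC transcript, a numbered cluster without a gene name, or a numbered region that the authors called nongenic; all but the last are called genic here. No host unit lay on more than 1 chromosome or strand. Peak numbers were missing within genic units, 17.6% of the numbers in the SRSF1 list and 19.9% in the SRSF2 list, so the lists hold part of the peaks that had been numbered. Read depth was not given, and the number of peaks is not a depth.

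Gene symbols came from a RefSeq table of assembly GRCm38.p6, used for names only. Of 2169 RefSeq accessions among the host units, 2155 matched a symbol. These genes hold 15.9% of all peaks; the 6420 cluster units hold most of the rest and were described by coordinate. Because the reference at hand was of another build, no exon, intron, untranslated region, splice site, cassette exon or sequence motif was assigned to any peak, and those planned comparisons were not run. The location of peaks was reduced to the authors' division into genic and nongenic.

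Overlap meant at least 1 nt shared on the same strand. The overlap function was checked against bedtools 2.31.1 and gave the same counts in both lists. Chance overlap came from 100 seeded random placements of the other list, keeping width, strand and chromosome, between the first and last peak on that chromosome. Placement within the same gene had been planned but needs an annotation. Closer controls were therefore set beside it: placement within 5 kb of each peak, and placement within the span that the peaks of both lists give a host unit, for units spanning at least 1000 nt. The last was chosen after seeing the data. Distances are between midpoints. Shared genes were counted as shared host units and as shared 10 kb windows, the latter against the product of the 2 numbers of windows over all 256749 windows, which include parts of the genome that are not transcribed. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only; peaks are not independent molecules. Standard errors come from a jackknife that leaves out each chromosome in turn. With 1 library per protein analysed here there is no replicate check, and no p-value between the proteins was computed.

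Genes were named by a rule fixed before the data were examined. It takes the 10 genes with most peaks of each protein, the 10 with the highest and the 10 with the lowest SRSF1 share among genes with at least 10 peaks, up to 4 members of each gene list, Srsf1 and Srsf2 themselves, and the 5 overlapping peak pairs with the highest smaller score. For peaks without gene names it takes 10 kb windows, 5 in place of 10. Pcbp1, Timp1, Calr and Eef1g were named outside the rule, after their values were seen. Srsf2 had no RefSeq-named unit with a peak and has no value here. Of 16 gene lists fixed beforehand, each with at least 3 named members was set against 10000 random lists of named genes matched on the number of peaks, where gene length had been planned. Of the 329 list symbols, 31 were matched through an older symbol in the same RefSeq table. The list of long noncoding RNAs and those of macrophage, endothelial, neuronal and skeletal muscle markers had 0 named members with a peak. This does not show that they were unbound, because most peaks lie in units without a name.

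The steps were tested on simulated data. A simulated SRSF2 list made with 30% of the SRSF1 peaks shared gave 30.03%. The shared peaks were exact copies and the others were placed at random on the chromosome, so this checks the counting alone. With 1 common SRSF1 share in all host units, the variance of the unit shares was 1.01 times that of binomial draws over 2948 units. With unit shares drawn with an SD of 10 percentage points it was 1.69 times. Alternatives were stricter score and overlap thresholds, merged peaks, fixed widths, a thinned list, and chromosomes left out. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.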

Results

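SRSF1 and SRSF2 are serine and arginine-rich proteins that bind RNA and take part in the choice of exons. The study asked how these proteins cooperate and compete in regulated splicing, and the peak lists allow a comparison of where each was bound in MEFs. The SRSF1 list held 50983 peaks and the SRSF2 list 56336, so that SRSF1 made up 47.5% of all peaks (95% interval 47.2 to 47.8). Peaks were narrow in both lists, with a median width of 19 nt, and covered 1.02 Mb for SRSF1 and 1.12 Mb for SRSF2. The median score was 8 in both lists, and 50.9% of SRSF1 peaks and 51.0% of SRSF2 peaks lay on the plus strand. A single library of each protein, from its own cell line, was analysed here, so the values describe these 2 libraries and have no replicate error.

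A minority of the listed peaks of each protein lay on a listed peak of the other, many times more than under random placement. The lists hold part of the numbered peaks, so these shares may miss partners that were not listed. Of the SRSF1 peaks, 19724 (38.7%, jackknife SE 0.821 percentage points) were overlapped by an SRSF2 peak on the same strand, and 19838 SRSF2 peaks (35.2%, SE 0.653) by an SRSF1 peak. On the opposite strand only 28 SRSF1 peaks (0.0549%) met an SRSF2 peak. Within overlapping pairs, 83.9% of the midpoints lay within 10 nt of each other and 445 of 20654 pairs had identical ends. Random placement of SRSF2 peaks within 5 kb gave an overlap of 1.94% (range 1.79 to 2.10 over 100 placements), so that the observed share was 19.98 times as large (SE 0.814), and placement within the host unit gave 22.6 times (SE 1.08). The planned placement anywhere on the chromosome gave 0.0675% and a ratio of 573 (SE 254) for SRSF1 and 578 (SE 264) for SRSF2. That ratio carries little precision, because 31.1% of the random overlaps with SRSF1 peaks fell on the mitochondrial chromosome. Without that chromosome the ratio was 829. No placement took account of exons or of coverage within a unit. The ratios therefore do not separate binding at common sites from coverage that both libraries share.

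The nearest peak of the other protein was often within reach of the same short stretch of RNA. For 48.6% of SRSF1 peaks an SRSF2 midpoint lay within 50 nt, for 54.7% within 100 nt and for 64.4% within 500 nt, with a median of 57.5 nt. For SRSF2 peaks the shares were 45.5%, 52.1% and 62.5%, with a median of 78.5 nt. Random placement within 5 kb put 4.51% of SRSF1 peaks within 50 nt and 31.3% within 500 nt, so the ratio fell from 10.8 at 50 nt to 2.06 at 500 nt. The limit given for the overlap ratios holds here too. At an offset of 40 nt there were 7.25 SRSF2 peaks per 100 SRSF1 peaks. Each protein around its own peaks gave 6.99 (SRSF1) and 8.21 (SRSF2). Of the SRSF1 peaks without an overlap, 26.1% still had an SRSF2 midpoint within 100 nt, and 90.3% lay in a host unit that also carried SRSF2 peaks. SRSF2 midpoints lay on both sides of SRSF1 midpoints in near-equal numbers, with 51.7% of those within 50 nt downstream, 51.1% at 50 to 100 nt, 49.5% at 100 to 200 nt and 49.5% at 200 to 500 nt. Neighbouring peaks are not independent, so no asymmetry is read from these shares.

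**Figure D1:**
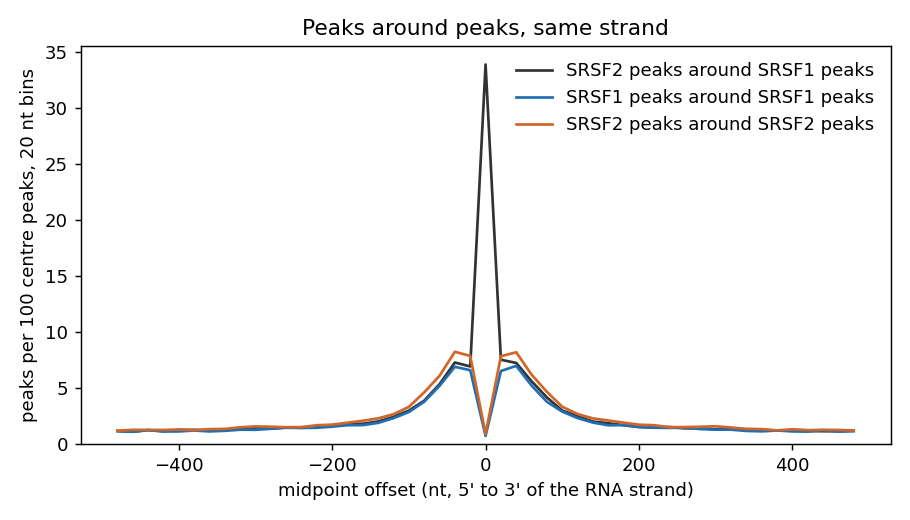
Number of peaks per 100 centre peaks (vertical axis, bins of 20 nt) by the distance between midpoints (horizontal axis, nt, in the direction of the RNA), for SRSF2 around SRSF1 and for each protein around its own peaks. The central bin holds 33.9 SRSF2 peaks per 100 SRSF1 peaks, and at distances of 20 nt and more the 3 curves have similar shapes.

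Peaks with high scores were shared more often than those with low scores. In the SRSF1 list, 65.7% of the peaks in the highest score class were overlapped (interval 64.7 to 66.6), against 19.5% in the lowest (18.8 to 20.3), with 5 classes of equal size. In the SRSF2 list the same classes gave 61.8% and 16.6%. Overlap needed only 1 nt, so a wider peak meets another more easily, and the classes were not matched on peak width. The lowest score per host unit ran from 4 to 168 in the SRSF1 list and from 4 to 205 in the SRSF2 list. The classes may therefore partly sort host units rather than sites. Across the 20654 overlapping pairs the authors' scores had a Spearman rho of 0.620 (SE 0.0141), where peaks are not replicates. The 5 pairs with the highest smaller score included regions that the authors called nongenic. They lay on chromosome 17 (plus strand, SRSF1 peak 39984448 to 39984498, scores 354 and 368 for SRSF1 and SRSF2, and 39984131 to 39984210, scores 270 and 313) and on chromosome 9 (minus strand, 78023111 to 78023216, scores 318 and 416). The other pairs were in an unnamed cluster on chromosome 19 (minus strand, 5796093 to 5796143, scores 290 and 321) and on the mitochondrial chromosome (plus strand, 2646 to 2678, scores 271 and 289). Without an mm9 annotation no transcript was assigned to these positions, so they may lie in known RNAs.

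**Figure D2:**
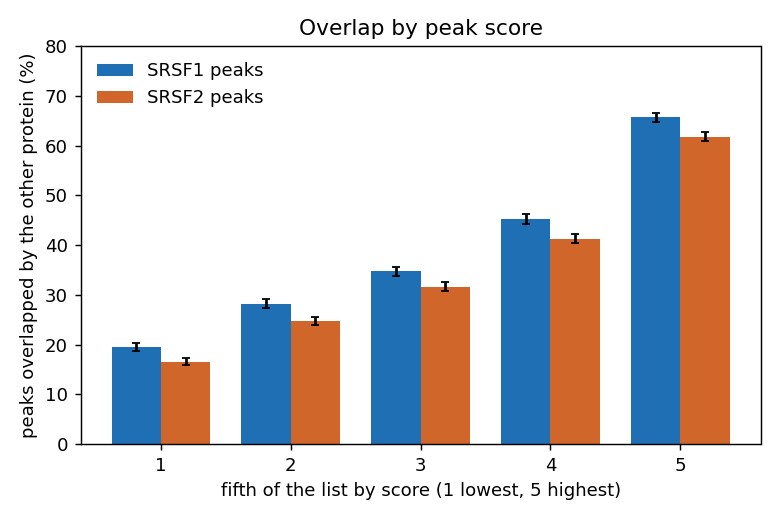
Percent of peaks overlapped by the other protein (vertical axis) in 5 equal score classes of each list (horizontal axis, 1 lowest, 5 highest), with exact 95% intervals as bars. The share rises from 19.5% to 65.7% for SRSF1 and from 16.6% to 61.8% for SRSF2.

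Most host units had peaks of both proteins. Of 8738 genic units with a peak, 6303 (72.1%) had peaks of both, 1291 had SRSF1 peaks alone and 1144 had SRSF2 peaks alone. Of the units with SRSF1 alone 65.6%, and of those with SRSF2 alone 65.0%, had a single peak and so could not have shown both. Units with both had a median of 9 peaks, against 1 in either other group. A unit with many peaks shows both proteins more easily, and no chance value was set beside the 72.1%. Peak numbers of the proteins had a Spearman rho of 0.727 across units, which are not replicates and were not matched on length or RNA level. In 10 kb windows, 14718 windows held both proteins where independent lists would share 1687, a ratio of 8.73 where full sharing would give 12.1. The windows include parts of the genome that are not transcribed, which lowers the chance value. Of the windows with SRSF1, 72.2% also held SRSF2, and 65.5% did so when at least 3 peaks of each were required (ratio 23.6, at most 36.0). Among genes with a symbol, 1422 had both proteins, 382 SRSF1 alone and 351 SRSF2 alone.

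Among genes with a symbol, which hold 15.9% of all peaks, those with most peaks were largely the same for both proteins, with 7 of the top 10 in common. Dync1h1, the cytoplasmic dynein heavy chain (chromosome 12, plus strand, peaks from 111839714 to 111905034), had most peaks of both proteins among these genes, with 76 SRSF1 and 116 SRSF2 peaks, an SRSF1 share of 39.6% (32.6 to 46.9). This interval includes the 42.6% of chromosome 12 as a whole. Zfhx4, a zinc finger homeobox transcription factor (chromosome 3, plus strand, 5218835 to 5415498), had 68 and 76 peaks, and Col1a1, a chain of type I collagen (chromosome 11, plus strand, 94797584 to 94813158), had 55 and 52. Flna, the actin crosslinker filamin A, had 45 SRSF1 and 51 SRSF2 peaks; Med13, a Mediator subunit, 44 and 40; Usp32, a ubiquitin protease, 34 and 47; and Lamc1, a laminin chain, 33 and 49. Smc5, a DNA repair ATPase, with 46 SRSF1 and 36 SRSF2 peaks, Xpo1, a nuclear export receptor, with 43 and 35, and the kinase gene Map4k4 with 34 of each were in the SRSF1 top 10 alone. Igf2r, the receptor for mannose-6-phosphate, with 31 SRSF1 and 52 SRSF2 peaks, Smg6, an endonuclease of nonsense-mediated decay, with 23 and 42, and Fam120a with 30 and 39 were in the SRSF2 top 10 alone.

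Few genes had an interval that excluded the overall share of 47.5%. Among 528 named genes with at least 10 peaks, the interval of 12 lay above it and that of 14 below. The intervals were not corrected for the number of genes, so counting error alone would put some of them outside. The genes named next are the extremes of these 528. The highest SRSF1 shares were those of Mybl1, a Myb-family transcription factor (9 SRSF1 and 1 SRSF2 peaks, 90.0%, 55.5 to 99.8), Fam168a (15 and 2, 88.2%, 63.6 to 98.5), Postn, the matrix protein periostin (13 and 2, 86.7%, 59.5 to 98.3), Erbb2, a receptor tyrosine kinase (10 and 2, 83.3%, 51.6 to 97.9), and Ndc1, a nuclear pore protein (9 and 2, 81.8%, 48.2 to 97.7). The intervals of Mboat1 (80%), Elavl1 (76.9%), Dgka and Rprd1a (75% each) and Slc30a4 (72.7%) included the overall share. The lowest shares were those of Wdr41 (2 SRSF1 and 14 SRSF2 peaks, 12.5%, 1.55 to 38.4), F2r, a thrombin receptor (2 and 12, 14.3%, 1.78 to 42.8), Man2a1, a Golgi mannosidase (3 and 17, 15.0%, 3.21 to 37.9), Oat, ornithine aminotransferase, and Rbm19, an RNA-binding protein (2 and 11 each, 15.4%, 1.92 to 45.5), Atf6, a transcription factor of the endoplasmic reticulum stress response (3 and 16, 15.8%, 3.38 to 39.6), and Atrn (3 and 13, 18.8%, 4.05 to 45.6). The intervals of Fermt2 (16.7%), Ero1a and Map2k1 (18.2% each) reached above it. Over all 2948 genic units with at least 10 peaks, 172 intervals excluded the overall share, where binomial draws with 1 common share gave 88.6 on average and at most 111 in 100 draws.

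**Figure D3:**
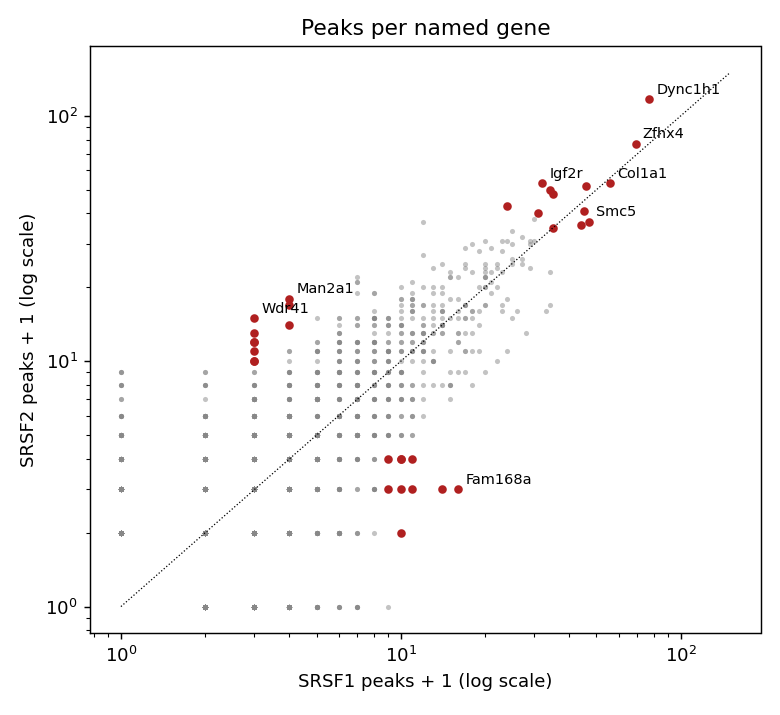
SRSF1 peaks (horizontal axis) against SRSF2 peaks (vertical axis) per gene with a symbol, both plus 1 on log scales, with the genes of most peaks and of the highest or lowest SRSF1 share in red and equal numbers on the dotted line. Dync1h1 stands at the top with 76 and 116 peaks, and Fam168a with 15 and 2 and Man2a1 with 3 and 17 lie away from the line.

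The intervals of the 4 lists of splicing factors included the overall share, at a precision that leaves room for differences, with 17 of their 94 genes named and bound. All 4 named SR protein genes, of 13 in the list, had both proteins, with 30 SRSF1 and 32 SRSF2 peaks together (48.4%, 35.5 to 61.4, at percentile 60.9 of random lists). Srsf1 itself (chromosome 11, plus strand, peaks from 87861241 to 87866520) had 11 SRSF1 and 12 SRSF2 peaks, of which 7 and 8 overlapped, and the highest-scoring peaks of both proteins fell on the same site, 87862619 to 87862710 for SRSF1 and 87862621 to 87862696 for SRSF2. Tagged SRSF1 was present in the SRSF1 line, and the lists do not tell RNA of its construct from that of the Srsf1 gene. Srsf3 had 9 and 10 peaks, Tra2b 6 and 7, and Srsf9 4 and 3. Of the 5 named hnRNP genes, out of 26, Hnrnpd had 21 and 23 peaks, Hnrnpul2 11 of each, Ptbp1 8 and 5, Hnrnph2 2 of each and Pcbp1 0 and 1, for a list share of 50% (38.9 to 61.1, percentile 72.2). The other splicing regulators Tial1 (15 and 15), Elavl1 (10 and 3) and Clk3 (3 and 5), 3 of 25 genes, gave 54.9% (40.3 to 68.9, percentile 84.8). The core spliceosome genes, 5 of 30, among them Snrpd3 (4 and 6), Snrpb (5 and 2), Snrpd1 (4 and 3) and Prpf4 (2 and 4), gave 50% (31.9 to 68.1, percentile 64.9).

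Of the 9 lists ranked against random lists, that of the extracellular matrix had the highest percentile and that of translation factors and chaperones the lowest. The percentiles were not corrected for the number of lists, and the extremes of 9 lists can reach such values by chance. Single-gene intervals excluded the overall share for 2 members of the matrix list and 1 of the other. The pooled intervals below do not cover differences between genes. The matrix list had 119 SRSF1 and 94 SRSF2 peaks in 7 genes (55.9%, 48.9 to 62.7, percentile 97.6), with Thbs1, thrombospondin, at 23 and 10, Postn at 13 and 2, Col1a1 at 55 and 52, and Col6a1 at 24 of each; Timp1, a metalloproteinase inhibitor, went the other way with 0 and 4. Leaving out each gene in turn gave 53.3% (without Thbs1) to 60.4% (without Col1a1). Translation factors and chaperones had 130 and 183 peaks in 10 genes (41.5%, 36.0 to 47.2, percentile 4.62), with Eif3c, an initiation factor subunit, at 11 and 36, Hsp90b1 at 30 and 39, and Pdia3 at 19 and 23. Eif4g2 at 22 and 15, Calr at 11 and 10 and Eef1g at 3 and 0 went the other way. Leaving out each gene in turn gave 39.1% (without Eif4g2) to 44.7% (without Eif3c).

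The intervals of the matrix list and of translation factors and chaperones excluded the overall share of 47.5%, while those of the remaining lists included it. Both exclusions were narrow, with bounds of 48.9% and 47.2%. They may rest on single genes, because the shares moved to 53.3% without Thbs1 and 44.7% without Eif3c, for which no interval was computed. Replication-dependent histone genes had 12 SRSF1 and 20 SRSF2 peaks in 15 genes (37.5%, 21.1 to 56.3, percentile 8.32), with H1f2 at 2 and 3, H2bc4 at 3 and 2, H2ac6 at 2 of each and H2ac4 at 1 of each. With only the members of at least 3 peaks, the histone share was 50%. All 15 had an SRSF2 peak and 8 an SRSF1 peak; many histone genes have near-identical copies, so the assignment of reads among them is uncertain, and most lay on chromosome 13, where SRSF1 had 43.5% of all peaks. The actin cytoskeleton list had 82 SRSF1 and 99 SRSF2 peaks (45.3%, 37.9 to 52.9, percentile 37.5), with Flna at 45 and 51, Actn4 at 18 and 19, Actb at 9 and 12 and Tpm4 at 3 and 7. Cytosolic ribosomal protein genes had 8 and 10 peaks (44.4%, 21.5 to 69.2, percentile 37.9), among them Rpl7a at 6 and 4, Rplp2 at 2 of each, Rpl5 at 0 and 3 and Rplp1 at 0 and 1. Leaving out each gene in turn gave 25% (without Rpl7a) to 53.3% (without Rpl5). Of the structural noncoding RNAs, Rmrp had 2 SRSF1 peaks and Rnu12 had 1 of each protein. The keratin gene Krt19, an epithelial marker, had 1 SRSF1 peak.

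Regions called nongenic held 7.91% of SRSF1 peaks and 8.84% of SRSF2 peaks, a difference of 0.927 percentage points (SE 0.181). The difference turned to -0.141 points in the upper 50% of each list by score. Of the nongenic peaks, 3.89% of those of SRSF1 (3.32 to 4.53) and 3.71% of those of SRSF2 (3.21 to 4.28) lay opposite to a genic unit's span.

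The SRSF1 share of the peaks differed between chromosomes. It was lowest on chromosome 12 at 42.6% (41.1 to 44.2) and chromosome 13 at 43.5% (41.9 to 45.2), and highest on chromosome 4 at 51.1% (49.9 to 52.4) and chromosome 18 at 50.4% (48.7 to 52.0). Over 20 chromosomes, leaving out Y and the mitochondrial one, the shares had an SD of 2.28 percentage points, and of 3.63 in the upper 50% of each list by score.

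**Figure D4:**
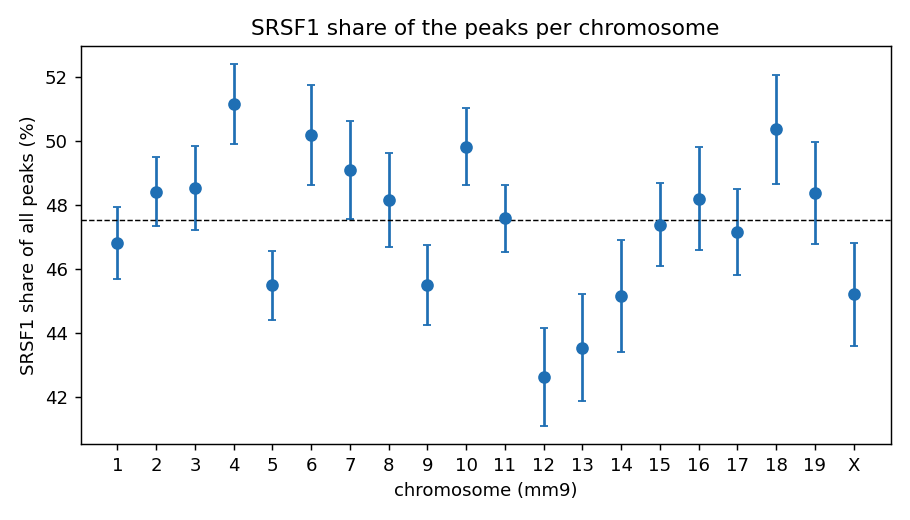
SRSF1 share of all peaks (vertical axis, percent) on 20 mouse chromosomes (horizontal axis), with exact 95% intervals as bars and the overall share of 47.5% as a dashed line. Chromosome 12 is lowest at 42.6% and chromosome 4 highest at 51.1%.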

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

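Observed overlap was at least 19.98 times the random overlap under each placement run, while the size of each share depended on the definition. The share of SRSF1 and SRSF2 peaks overlapped was 37.2% and 33.8% when 50% of the shorter peak had to be shared, 48.6% and 45.5% for midpoints within 50 nt, 48.5% and 45.3% with every peak set to 50 nt, 40.3% and 37.6% with peaks merged, and 43.5% and 39.4% in the upper 50% by score. Thinning the longer list gave 35.1% for SRSF1. Leaving out 1 chromosome gave 38.4% to 39.0% and 35.0% to 35.4%. The ratio to random overlap fell to 22.6 and 22.8 within the host unit, 19.98 and 20.03 within 5 kb, and 35.7 and 38.2 with the whole list shifted by 5000 nt; these placements follow the host unit or its surroundings, which alone raises chance overlap. Without mitochondrial peaks it was 829 and 845. The share within 50 nt was 44.1% and 41.3% with peaks merged and 51.6% and 47.8% in the upper 50%. Units with both proteins made up 67.0% with at least 3 peaks and 64.7% in the upper 50%, and the window ratio was 23.6 and 16.9, where fewer windows raise the highest possible ratio from 12.1 to 36.0 and 24.1. The nongenic difference turned to -0.141 points in the upper 50%, and the SD of the chromosome shares rose to 3.63; the cause was not tested. All 36 alternatives for gene lists stayed within the list's own interval, which is wide for lists with few peaks. Chosen after seeing the data were the host-unit and shifted placements, the gene lists with members left out, all alternatives for score correlations, those for the SD of the chromosome shares except merging, and the runs without mitochondrial peaks (with Y where both were left out) other than for the peak numbers. Alternatives that need gene models, gene lengths or sequence were not run. The number of peaks limits shares of single genes, and read depth is unknown.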

Other observations

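The tests of counting error and of peak score below were chosen after related values had been seen; the other tests were written before their results. Of the 5 densest 10 kb windows of each protein, 3 were in common. Unnamed clusters on chromosome 15 held 41 SRSF1 and 50 SRSF2 peaks from 77590001 to 77600000, and 39 and 45 from 82680001 to 82690000, and the mitochondrial window from 1 to 10000 held 38 and 43. Among the SRSF1 windows alone, one on chromosome 19 from 5790001 to 5800000 held 39 and 30. Another, on chromosome 17 from 39980001 to 39990000, where the authors called the host units nongenic, held 38 and 34. Among the SRSF2 windows alone, one on chromosome 19 from 9070001 to 9080000 held 27 and 39 and one on chromosome 1 from 34240001 to 34250000 held 27 and 38. Among windows with at least 10 peaks, the highest SRSF1 share was in Fam168a on chromosome 7 from 107980001 to 107990000, with 11 SRSF1 peaks and 0 SRSF2 peaks, followed by an unnamed cluster on chromosome 9 from 79520001 to 79530000 with 14 and 1. The lowest was an unnamed cluster on chromosome 7 from 52750001 to 52760000, with 1 and 11, with 4 windows at 1 and 10 next, in F2r on chromosome 13 from 96370001 to 96380000, on chromosome 17 from 88380001 to 88390000, and on chromosome 9 from 42060001 to 42070000 and from 115150001 to 115160000.

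The mitochondrial chromosome carried 63 SRSF1 and 79 SRSF2 peaks. Of these, 57 and 64 lay on the plus strand, with median scores of 51 and 60.5, against medians of 17.5 and 13 on the minus strand. An overlap with the other protein was found for 81.0% of the SRSF1 peaks (69.1 to 89.8) and 63.3% of the SRSF2 peaks (51.7 to 73.9). Random overlap is frequent here too. Under placement on the chromosome, 31.1% of all random overlaps with SRSF1 peaks and 31.7% of those with SRSF2 peaks fell on this chromosome. No chance value for it alone is given, so these shares do not separate binding from coverage that both libraries share.

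The SRSF1 share differed between chromosomes. Reassigning whole host units to chromosomes 10000 times gave a spread as large in a share of 0.0001, the smallest these draws can give, which argues against chance placement of units with differing shares. Without the units of 50 or more peaks the SD was 1.12 times its value, which argues against a few peak-dense units. The SRSF1 shares of both parts of a chromosome, split at the middle of its peaks, rose and fell together over 20 chromosomes, with Pearson r = 0.722 (bootstrap interval 0.486 to 0.884, permutation p = 0.00026, adjusted 0.000347) and Spearman rho = 0.689 (permutation p = 0.00096, adjusted 0.00096), two-sided, and r = 0.706 without the 2 chromosomes farthest from the median. A difference along whole chromosomes between the libraries, such as chromosome number in the MEF lines, is therefore a candidate explanation, and no biological explanation was tested.

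The SRSF1 share also differed between host units by more than counting allows, with a variance 1.21 times that of binomial draws against at most 1.09 in 1000 simulations. Shares in the upstream and downstream parts of a unit went together across 1435 units with at least 20 peaks, with Spearman rho = 0.235 (bootstrap interval 0.185 to 0.283) and Pearson r = 0.250, both with a permutation p of 1e-05, the smallest possible, and 2e-05 after adjustment over the 4 correlations computed. Pearson r was 0.239 without the 2 units farthest from the median; units are not replicates. A unit-wide difference between the libraries, such as another RNA level in the cell lines, may account for this, but a preference of a protein for whole transcripts would give the same relation and stays open.

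Most peaks of each protein had no overlapping peak of the other in the lists. Within genic units, 17.6% of the peak numbers were missing from the SRSF1 list and 19.9% from the SRSF2 list. Some unshared peaks may therefore face a numbered peak that was not listed, and this was not tested. Ranked by score within their own host unit, over 1393 units with at least 10 SRSF1 peaks, 69.7% of the SRSF1 peaks in the top class and 30.4% in the bottom class were overlapped, a difference of 39.4 percentage points. Peaks near the calling threshold that were missed in the other library may account for part of the unshared peaks, though strong sites bound by both proteins would give the same relation. Peak width was not held equal between these classes either. Among 26826 SRSF1 peaks in host units with at least 10 SRSF2 peaks, 48.9% were overlapped, 10.2 points more than among all, which leaves open how far poor coverage of the host unit in the other library contributes. In such units lay 7101 SRSF1 peaks of the highest score class, here taken over the whole list and not within the unit. Of these, 28.7% were not overlapped. The lowest score differed between host units, so this class can hold peaks that are the weakest of their own unit. In Srsf1 the lowest SRSF1 score was 17, while the class starts at 11. The 28.7% therefore does not show strong unshared sites, and sites bound by 1 protein alone remain among the open explanations.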
